A study of Homo sapiens with 3 samples.

How the data were processed

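Genomic DNA of 3 NUGC3 cultures carrying a GeCKO knockout library was amplified in a 2-step PCR and sequenced on an Illumina instrument, per the labels' protocols. Each of the 3 conditions (DMSO day 0, DMSO day 14 and 10 nM RTX day 14) was 1 library. The authors deposited 3 guide-level tables, 1 for each pair of libraries, made with MAGeCK 0.5.7, per the submitters' processing notes, which also name the build hg19. How reads were matched to guides is not given in the sources used here.

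Per the file headers, each table holds a control and a treatment value per guide. The values behave as a signal of guide abundance, read counts that the authors divided by 1 size factor per library within each pair. Whole reads were recovered by dividing each column by the value of 1 read. Within a tolerance of 0.1, at least 99.9968% of the values of every column came out whole, and the totals of a library were the same in the 2 tables that hold it. The deposited tables also give the authors' one-sided p-values and FDR (q-values) per guide, from a variance model over 2 single libraries. In the authors' deposited table of RTX over DMSO, 8738 guides were higher and 2699 lower at an FDR under 0.05, and 136 of the 1000 non-targeting guides (13.6%) were among the calls. In the authors' deposited tables the non-targeting share was 18.5% for DMSO over day 0 and 15.0% for RTX over day 0, so these guide calls served only as an alternative ranking.

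The log2 ratio of each guide was computed from the deposited normalized values with a pseudocount of 5, for 62610 of 62916 guides with at least 10 normalized reads at day 0. A ratio on this scale understates the change of guides with few reads. A gene's score is the median over its guides, and ranges are over guides. The tables hold 18308 genes with 3 guides. Left out were 23 date-like names, which a spreadsheet makes of some symbols, with 72 guides. The main test ranked guides in each direction and combined ranks within a gene by robust rank aggregation with the top 0.25 of ranks. The one-sided p came from 10000000 random draws of the same number of ranks, called a permutation p here, and was adjusted by the Benjamini-Hochberg method over 20150 genes with at least 2 guides, with a threshold of 0.05. The smallest p the draws can give is 1e-07. These p measure only how far the guides of a gene agree between 2 libraries. They compare those libraries and cannot see variation between cultures.

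The 25 gene lists were fixed before the data were examined, and so were the test, the filters, the alternatives and the rule for named genes. A list's median score was set against 10000 random lists matched on deciles of day 0 abundance and on guide number. Lists matched also on the DMSO over day 0 score used deciles of that score and pairs of abundance deciles. Guide number was not matched in these, and genes within the lowest decile can still differ in how far they were lost. The percentile describes these libraries and is no p, and percentiles under 2.5 or over 97.5 were taken as past the limits. Intervals of medians are 95% bootstrap intervals from 2000 resamples of genes and do not cover differences between cultures. Beside calls over all genes, calls adjusted over the list alone were counted. Another 5 lists were added after the data were examined. The named genes were, by lowest p with all guides of 1 sign, 15 enriched and 10 depleted in RTX over DMSO, 10 depleted and 5 enriched in DMSO over day 0, and 5 enriched and 5 depleted in RTX over day 0. To these came the members of the Mediator, cohesin, MYC, antifolate and folate lists that passed in any comparison, and 19 genes fixed by name. Not every named gene or list is printed.

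Alternatives were pseudocounts of 1 and 20, no filter, a filter of 50 reads, the top 0.1 of ranks, ranking by the authors' p-values, the probability of the second-best guide, genes with at least 3 guides, scaling to the non-targeting guides or to equal totals, and the mean in place of the median of guides. Chosen after the data were examined were the counts without chromosome 21 and a count test, edgeR's exact test on the recovered reads with 1 dispersion from the non-targeting guides, whose ranks replaced the log2 ratio. With 1 dispersion its ranks nearly repeat those of the log2 ratio (Spearman's rho over guides 0.9996 to 0.9998), so it is not independent evidence. Gene order and chromosomes were taken from the RefSeq table of GRCh38.p14, which placed 19353 of 20449 symbols, 2085 of them through a synonym. Because the authors' build is hg19, no coordinates are given.

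The gene test was tested on simulated data with the spread of the non-targeting guides for RTX over DMSO, with 200 of 20150 genes changed. At a log2 change of 2 it recovered 76% of 50 enriched and 76% of 50 depleted genes, and at a log2 change of 1 it recovered 6% and 4%. It called 2 unchanged genes. Of 200 random lists of 30 unchanged genes, 5 fell under percentile 2.5 and 4 over 97.5. With 0.25 added to every member, 142 lay over 97.5. PCR reads carry no molecular identifiers, so counting error is a lower bound. Tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and edgeR 4.0.16.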

Results

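NUGC3, an established human gastric cancer cell line, carried a pooled GeCKO library, in which each cell receives a guide RNA that directs Cas9 to cut 1 gene. The number of reads of a guide in genomic DNA then measures how many cells with that guide remain. The 3 libraries were cells at day 0, cells kept in the solvent DMSO to day 14 and cells kept in 10 nM RTX to day 14. The labels do not spell out RTX, and the series title concerns antifolate sensitivity of gastrointestinal cancer together with MYC, cohesin and Mediator. The sample titles were used for the groups, because a treatment note describes the day 0 group as treated for 14 days. Each condition was 1 library, so no difference between conditions has a replicate check.

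Sequencing depth was similar in the 3 libraries. The day 0 library held 16547572 reads over 62916 guides, with a median of 230 reads per guide and 24 guides at 0. The DMSO day 14 library held 18805737 reads, a median of 251 and 236 guides at 0. The RTX day 14 library held 17344507 reads, a median of 232 and 185 guides at 0. The Gini index, which is 0 when all guides are equally abundant, was 0.354 at day 0, 0.393 in DMSO and 0.39 in RTX. The most abundant guide of the RTX library targeted SLC19A1 and took 43111 reads, which was 0.249% of the library. The top 1% of guides took 3.61%, 4.17% and 4.58% of the reads at day 0, in DMSO and in RTX.

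Guides without a target in the genome showed how far abundance drifted without a knockout. The SD of the log2 ratio over the 1000 non-targeting guides was 0.65 for RTX over DMSO, 0.53 for DMSO over day 0 and 0.57 for RTX over day 0, where counting error alone would give 0.21, 0.20 and 0.21. Their median was -0.10, 0.20 and 0.11 in the same comparisons, while the median of all guides was 0 by construction, so every log2 ratio here is relative to all guides. Scaling to the non-targeting guides turned the sign of 19 of 87 list medians, of which 17 had intervals that include 0, and scaling to equal totals that of 6. Pairs of guides of the same gene correlated only weakly across 20150 genes, with Pearson's r of 0.0926, 0.148 and 0.093 and Spearman's rho of 0.0659, 0.0936 and 0.0687. The highest r in 100 reshufflings of guides over genes was 0.0178, 0.0151 and 0.0171. Genes are not independent replicates in these correlations.

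The comparison of RTX with DMSO at day 14 asks which knockouts favour or hinder growth in the drug. Guides against SLC19A1, the reduced folate carrier that takes antifolates into the cell, rose more than those of any other gene past the threshold, with a median log2 ratio of 5.26 and a range over its 3 guides of 4.95 to 6.82 (adjusted permutation p = 0.002015). Their reads were 87, 284 and 414 in DMSO and 2578, 10090 and 43111 in RTX. Guides against FPGS, the enzyme that adds glutamates to folates and antifolates and so keeps them in the cell, rose by a median log2 ratio of 3.46 over 3 guides, with a range of 2.40 to 7.47 (adjusted permutation p = 0.00369). These were the 2 members of the 7-gene list of antifolate uptake and polyglutamation that passed, both over all genes tested and adjusted over the list alone, and the list's median was 0.01.

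**Figure D1:**
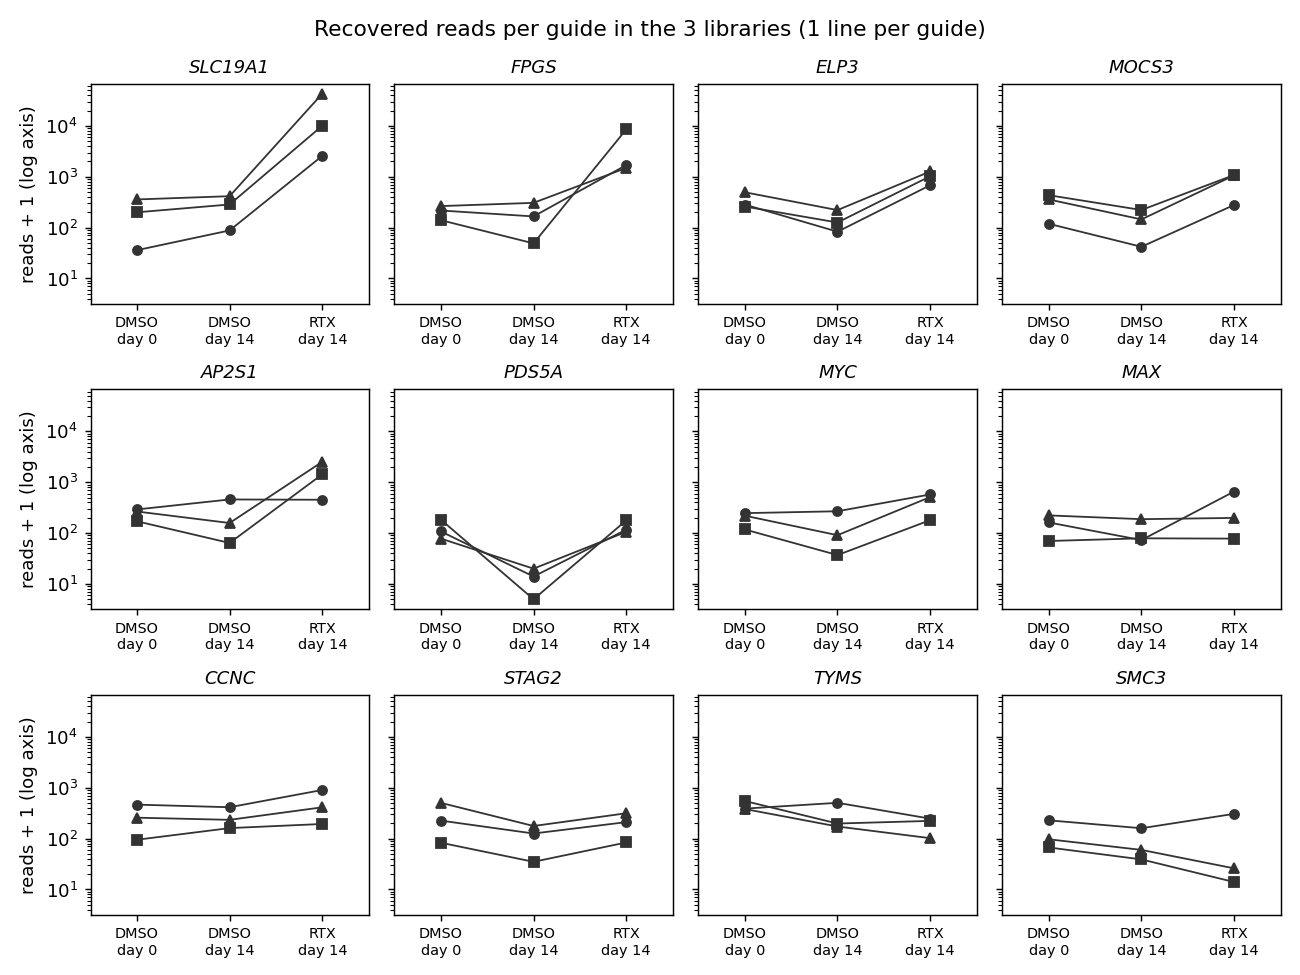
Recovered reads of each guide (log axis, 1 added) in the DMSO day 0, DMSO day 14 and RTX day 14 libraries for 12 named genes, with 1 line per guide and 1 library per condition. All 3 guides of SLC19A1 and of FPGS lie higher in RTX than in both DMSO libraries, and the 3 PDS5A guides fall in DMSO and lie near their day 0 reads in RTX.

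In all, 16 of 20150 genes were enriched in RTX over DMSO. Besides SLC19A1 and FPGS they included ELP3 and ELP6, subunits of the Elongator complex that modifies transfer RNA, with median log2 ratios of 3.12 and 2.88. MOCS3, which supplies sulfur for transfer RNA thiolation, stood at 2.75. POLR1E and ZNRD1, subunits of RNA polymerase I, stood at 2.93 and 2.81. UTP18 and FCF1, factors of ribosomal RNA processing, stood at 2.10 and 2.11. AP2S1, a subunit of the clathrin adaptor AP-2, stood at 4.10, although 1 of its 3 guides was at 0.12. DHX33, an RNA helicase, stood at 4.75 with a guide range of 0.71 to 5.40. Its guides had 128, 297 and 233 reads at day 0, 4, 281 and 0 in DMSO and 220, 420 and 195 in RTX. The high ratio therefore rests on few reads in DMSO, and the median log2 ratio of RTX over day 0 was 0.49 without passing. CUL2, the scaffold of a ubiquitin ligase, stood at 2.30, and FAM96B, a factor of cytosolic iron-sulfur assembly, at 2.01. WDR4, part of a transfer RNA methyltransferase, stood at 1.81, but lies on chromosome 21, whose genes were shifted as a block. The last called gene, PGD of the pentose phosphate pathway, had only 2 guides. The adjusted permutation p of ELP3, ELP6 and DHX33 was 0.003022, and that of WDR4 was 0.0318. With a pseudocount of 1, AP2S1, ZNRD1 and WDR4 no longer passed, and with 20 UTP18 did not. Judged by the second-best guide of each gene, 4 genes passed.

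Of these 16 genes, 6 were also among the 40 depleted in DMSO over day 0, namely DHX33, ELP6, FAM96B, PDS5A, POLR1E and UTP18. Both comparisons use the DMSO day 14 library, so part of this overlap can come from that library's chance values. Across 20150 genes, the scores of the 2 comparisons had a Pearson's r of -0.558, a Spearman's rho of -0.501 and a covariance of -0.113. In 100 simulations of unchanged libraries with the spread of the non-targeting guides, r was -0.447 and the covariance was -0.0674. In RTX over day 0, DHX33, ELP6, FAM96B, PDS5A, POLR1E and UTP18 had median log2 ratios of 0.49, 1.165, 0.14, 0.10, 1.02 and -0.09. None of these 6 genes passed there.

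No gene was depleted in RTX over DMSO. The lowest adjusted permutation p was 0.8833, and 1044 genes had an unadjusted p under 0.05, where chance would give about 1 in 20 of the genes tested. The count test on recovered reads also called 0. Among genes with all guides of 1 sign, the depleted genes of lowest p, none of which passed, included ANKRD53 with a median log2 ratio of -2.16, SUPT5H, a transcription elongation factor, with -1.51, LY6G6C with -1.31, BCAS4 with -1.16, SNRK with -1.14, the nucleoside transporter SLC29A3 with -1.11 and the integrin ITGAV with -1.04. C16orf55 and hsa-mir-2052 were also among them and rested on 1 guide each, with lowest guides of -3.94 and -3.58.

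The gene groups named in the series title were examined as lists, and differences between the lists were not tested. The 33 measured Mediator genes, which encode the bridge between transcription factors and RNA polymerase II, had a median log2 ratio of 0.23 in RTX over DMSO (95% bootstrap interval over genes 0.15 to 0.47), at percentile 99.5 of 10000 matched random lists. No member passed the test, over all genes or adjusted over the list alone. Against random lists matched also on the DMSO over day 0 score, the percentile was 63.7. In RTX over day 0, lists so matched put Mediator at percentile 97.4, just inside the limits. The ratio there does not use the DMSO day 14 library, but the matching on the DMSO score does. Against lists matched without that score, Mediator was at percentile 72.0 in RTX over day 0. The 7 genes of the Mediator kinase module had a median of 0.19 at percentile 88.3 (98.8 with the mean of guides). Of its members, CCNC stood at 0.95, MED12 at 0.47, CDK8 at 0.44, CDK19 at 0.19, MED12L at 0.09, MED13 at -0.01 and MED13L at -0.18, with none past the threshold. MED15, outside the module, stood at 0.38.

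The 14 cohesin genes had a median of -0.06 in RTX over DMSO, at percentile 34.1. PDS5A, a regulator of cohesin on chromatin, passed with 2.87 and a range of 2.32 to 4.44 (adjusted permutation p = 0.00403), and adjusted over the list alone STAG2 passed with it. STAG2 stood at 0.95, RAD21 at 0.68, SMC1A at 0.19, NIPBL at 0.04, STAG1 at -0.25 and SMC3 at -0.97. The PDS5A guides had 107, 183 and 77 reads at day 0, 13, 4 and 19 in DMSO and 116, 177 and 105 in RTX. The median log2 ratio of PDS5A in RTX over day 0 was 0.10. STAG2 stood at -0.10 in RTX over day 0 and at -1.30 in DMSO over day 0.

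The 12 genes of the MYC network had a median of -0.01 at percentile 49.5. All 3 MYC guides were higher in RTX than in DMSO, with a median log2 ratio of 2.30 and a range of 1.23 to 2.58, but the adjusted permutation p over all genes was 0.1586. Adjusted over the list alone, 1 gene of the network was enriched (MYC) and 1 was depleted (MGA, whose guides ranged from -3.85 to 1.41). MAX, the partner of MYC, stood at 0.22, with 1 guide at 3.24. TYMS, a target of antifolates, stood at -0.61, while TK1, the kinase that salvages thymidine, stood at -0.29. The 24 genes of folate one-carbon metabolism had a median of -0.07 at percentile 24.3, and adjusted over the list alone 2 were enriched, among them the chromosome 21 gene GART, and 0 over all genes. The 26 genes of thymidylate and deoxynucleotide supply had a median of -0.04 at percentile 33.0.

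Knockouts of genes that cells need were less depleted in RTX than in DMSO for several groups. The 75 cytosolic ribosome genes had a median of 0.66 in RTX over DMSO (interval 0.50 to 0.78), above all 10000 matched lists, with 8 genes adjusted over the list alone and 0 over all genes. The 31 proteasome genes had a median of 0.39 (interval 0.29 to 0.59) at percentile 99.99. The 12 genes of RNA polymerase II had one of 0.51 at percentile 99.96, but its interval of -0.08 to 0.64 includes 0. The 65 genes of the mitochondrial ribosome and respiratory complex I stood at 0.27 (interval 0.04 to 0.40), above all matched lists. Against lists matched also on the DMSO over day 0 score, the ribosome still lay above all 10000. The proteasome was then at percentile 79.0, RNA polymerase II at 68.4 and the mitochondrial list at 58.6. In RTX over day 0, lists so matched put the ribosome at percentile 92.6 and the proteasome at 3.9. RNA polymerase II was there at 10.0 and the mitochondrial list at 0.41. Equal loss in DMSO would make the percentiles of both comparisons nearly alike, so loss was not fully matched. The 41 DNA replication genes stood at 0.14, at percentile 95 (9.23 when matched also on the DMSO over day 0 score), and the 39 of the spliceosome core at 0.15, at percentile 95.7 (7.07 when so matched). Among chromatin lists, the 20 genes of SAGA and histone acetylation stood at 0.37, at percentile 99.9, with none past the test, and the 19 SWI/SNF genes at 0.21, at percentile 97.2, with 0 over all genes and 2 adjusted over the list alone (SMARCB1 and ACTL6A), and at 97.53 without the genes of chromosome 21, past the upper limit. Adjusted over the list alone, 1 gene each of the proteasome (PSMD4), DNA replication (GINS4) and mitochondrial (MRPL39) lists was enriched. The PSMD4 guides ranged from 0.56 to 5.00 around a median of 0.68, and MRPL39 is a gene of chromosome 21, whose genes were shifted as a block. Of CTCF and enhancer looping, 1 gene was enriched and 1 depleted when so adjusted. In each of these lists, 0 genes passed over all genes. The 27 genes of homologous recombination stood at 0.28, at percentile 99.9 (94.6 without the filter on day 0 reads), with none past the test.

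The other fixed lists given here lay, in RTX over DMSO, between percentiles 1.28 and 95.6. The 364 olfactory receptor genes, taken as genes a gastric line does not use, were at -0.06, percentile 1.28, and at 0.0417 when scaled to the non-targeting guides (percentile 15.6 against lists matched also on the DMSO over day 0 score). The ATR-CHK1 checkpoint was at 0.04 and percentile 64.4, and base excision repair at -0.09 and 23.8. Growth suppressors were at 0.15 and 95.6 (98.7 with the mean of guides, and 98.7 when matched also on the DMSO over day 0 score), apoptosis effectors at 0.02 and 62.4, CTCF and enhancer looping at 0.04 and 61.0, and drug efflux at -0.17 and 14.1. The 1654 microRNA genes had a median of 0.00428, with no percentile because they fill their own class of guide number.

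**Figure D2:**
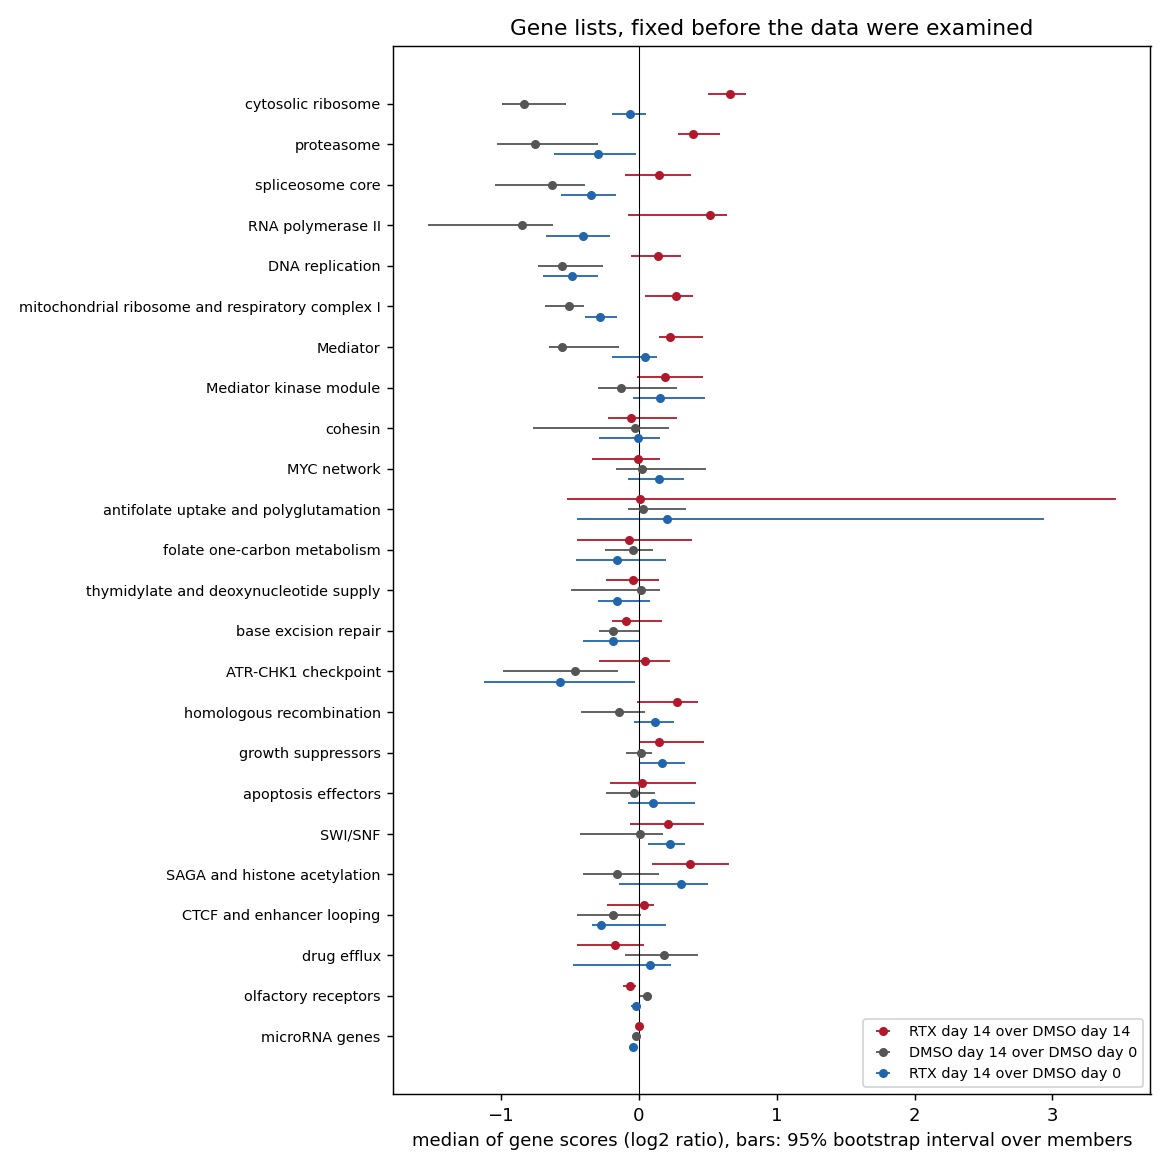
Median of the gene scores (log2 ratio, horizontal axis) of gene lists fixed before the data were examined, in the 3 comparisons, with bars for the 95% bootstrap interval over members. The cytosolic ribosome lies at -0.83 in DMSO over day 0, at -0.06 in RTX over day 0 and at 0.66 in RTX over DMSO.

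The comparison of DMSO at day 14 with day 0 shows which knockouts were lost without drug. In all, 40 of 20150 genes were depleted and 0 enriched. CDIPT, which makes phosphatidylinositol, had a median log2 ratio of -3.41, DHX33 of -4.00, POP5, a subunit of RNase P, of -2.76, SRP54 of the signal recognition particle of -2.42, and RAD9A of the checkpoint clamp of -2.45. NMT1, the N-myristoyltransferase, stood at -2.36, SS18L2 at -2.29, DONSON, a replication factor on chromosome 21, at -2.22, and STX4 at -2.15. The microRNA gene hsa-mir-566 stood at -2.96. A guide that matches several places cuts at each of them, so the losses of the 4 microRNA genes called and of the multi-copy genes WASH1 and GOLGA6L4 are uncertain as effects of those genes. The lowest adjusted permutation p was 0.01295. With a pseudocount of 1, 13 genes were depleted, and by the second-best guide 5.

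The lists of core genes were depleted as groups in DMSO over day 0. The 75 ribosome genes had a median of -0.83, with 28 depleted adjusted over the list alone and 1, RPL3, over all genes. The proteasome stood at -0.75 with 10 of 31 genes adjusted over the list alone, the spliceosome core at -0.63 with 7 of 39, RNA polymerase II at -0.84 with 5 of 12 and DNA replication at -0.56 with 10 of 41, of which CDC45 passed over all genes. All 5 lists lay below every one of 10000 matched lists, as did the 33 Mediator genes at -0.55 and the mitochondrial list at -0.50, which had 13 of 65 genes adjusted over the list alone. No Mediator gene passed. The ATR-CHK1 checkpoint stood at -0.46, at percentile 0.06, where RAD9A passed. Cohesin was at -0.02 and percentile 41.5 and the MYC network at 0.02 and percentile 58.2 (-0.17 when scaled to the non-targeting guides), while PDS5A at -2.77 was the only cohesin gene past the threshold over all genes and STAG2 at -1.30 and SMC3 at -0.81 passed adjusted over the list alone. MYC stood at -1.39 and TYMS at -1.28 without passing.

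No gene was enriched in DMSO over day 0, where 1074 genes had an unadjusted p under 0.05, the count test on recovered reads called 0 and the lowest adjusted permutation p was 0.8441. The 5 genes of lowest p with all guides of 1 sign were C16orf55, which rested on 1 of 2 guides, CBLN2 at 0.89, TSG101 at 1.37, RPS6KA5 at 0.85 and STEAP4 at 0.99. The olfactory receptors stood at 0.06, at percentile 99.8, and at -0.13 when scaled to the non-targeting guides.

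RTX at day 14 against day 0 does not involve the DMSO day 14 library. Here 10 genes were enriched. SLC19A1 stood at 6.01 with a guide range of 5.62 to 6.89, FPGS at 2.94 with 2.47 to 5.88 and AP2S1 at 3.03 with 0.62 to 3.22. ELP3 and MOCS3 were also called. These 5 genes were enriched in both comparisons that involve RTX, and both use the RTX library, so the overlap is not independent evidence. The other 5 were ADARB1, PDXK, HLCS and TCP10L of chromosome 21 and the kinase JAK1. ADARB1 stood at 1.58 and PDXK at 2.42. Without the genes of chromosome 21, 5 genes were enriched.

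No gene was depleted in RTX over day 0, with a lowest adjusted permutation p of 0.0544, 35 genes under 0.25 and 1143 at an unadjusted p under 0.05; the count test on recovered reads called 4. Among genes with all guides of 1 sign, the lowest p belonged to TXN, thioredoxin, at -2.29, TRAPPC4 of vesicle transport at -3.05, ATP6V0C of the vacuolar proton pump at -1.69, CNOT3 of the deadenylase complex at -1.91 and MAD2L1 of the spindle checkpoint at -2.02. The ATR-CHK1 checkpoint list stood at -0.57, below all 10000 matched lists, with 5 of 14 genes (CHEK1, RAD17, RAD9A, HUS1 and TIMELESS) depleted adjusted over the list alone and 0 over all genes. DNA replication stood at -0.48, also below all matched lists, while RNA polymerase II stood at -0.40 and percentile 0.07, the spliceosome core at -0.34 and the mitochondrial list at -0.28, both below all matched lists, the proteasome at -0.29 and percentile 0.03, and the ribosome at -0.06 and percentile 10.3. Mediator was at 0.04 and percentile 72.0, cohesin at -0.00288 and 51.1, the MYC network at 0.15 and 92.6, and SAGA and histone acetylation at 0.31 and 99.99. MYC stood at 1.20, CCNC at 0.94 and SMC3 at -1.76 without passing over all genes.

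Gene scores were also compared by chromosome, which was chosen after the data were examined. The 221 genes of chromosome 21, which carries SLC19A1, had a median log2 ratio of 0.73 in RTX over DMSO (95% bootstrap interval 0.66 to 0.79) and 0.69 in RTX over day 0 (0.64 to 0.74). In DMSO over day 0 their median was 0.03 (-0.04 to 0.07). Every other autosome and the X lay between -0.12 and 0.07 in RTX over DMSO and between -0.14 and 0.07 in RTX over day 0. Of the chromosome's guides, 82.8% were above 0 in RTX over DMSO. Chromosome 9, which carries FPGS, had a median of -0.01.

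**Figure D3:**
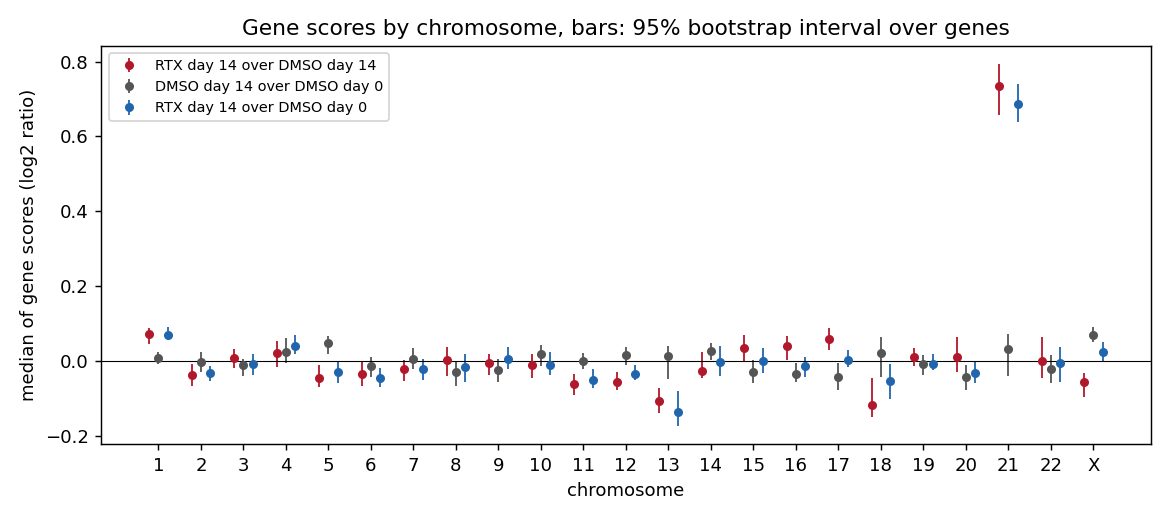
Median gene score (log2 ratio, vertical axis) by chromosome in the 3 comparisons, with bars for the 95% bootstrap interval over genes. Chromosome 21 stands at 0.73 in RTX over DMSO and 0.69 in RTX over day 0 and at 0.03 in DMSO over day 0.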

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

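The counts without chromosome 21 and the count test were chosen after the data were examined. No gene was depleted in RTX over DMSO or enriched in DMSO over day 0 under any of the 10 alternatives. The 16 genes enriched in RTX over DMSO became 26 when guides were ranked by the authors' p-values, 15 of them shared, and 4 by the second-best guide, all shared. The 40 genes depleted in DMSO over day 0 became 13 with a pseudocount of 1 and 5 by the second-best guide. Ranked by the authors' p-values 39 were depleted, of which only 14 were shared. The 10 genes enriched in RTX over day 0 became 23 with a pseudocount of 20, 21 with at least 50 day 0 reads, 26 with the authors' p-values and 5 without chromosome 21, which removes 5 of them by construction. The 0 genes depleted in RTX over day 0 became 4 with a pseudocount of 20, 2 with at least 50 day 0 reads, 14 with the authors' p-values, 2 by the second-best guide and 4 with the count test. The percentile of Mediator in RTX over DMSO went from 99.5 to 63.7 when lists were matched also on the DMSO score, and that of the kinase module from 88.3 to 98.8 with the mean of guides. For the changes other than the one without chromosome 21, the cause was not tested. Scaling to the non-targeting guides turned the olfactory receptors to 0.0417 in RTX over DMSO and to -0.13 in DMSO over day 0. It shifts all genes alike, so it cannot test the percentiles. Leaving out the most extreme guide moves a median of 3 guides by less than their SD by construction, so it shows nothing about the stability of single genes. No paired analysis was possible because each condition is 1 library. In simulated data for RTX over DMSO, the test recovered 6% of genes enriched and 4% of genes depleted by a log2 change of 1, so genes that did not pass are not shown to be without effect.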

Other observations

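The lists in this part, the order along chromosome 21 and the tests of the part beyond SLC19A1, of a common reduction of divisions and of the transfer RNA genes were chosen after the results were seen. Of 14 genes that modify the wobble uridine of transfer RNA (Elongator and the thiolation pathway), the median log2 ratio was 1.19 in RTX over DMSO (95% bootstrap interval 0.95 to 2.75), -0.78 in DMSO over day 0 and 0.89 in RTX over day 0 (0.64 to 1.17). In RTX over day 0 this list lay above all 10000 matched lists. Values of 7 of its genes had been seen before the list was made, so this rank is no independent support. ELP2 stood at 3.08, KTI12 at 2.43, CTU2 at 1.93 and IKBKAP, the largest Elongator subunit, at 1.29 in RTX over DMSO, while URM1 stood at -0.19. NFS1, which also serves iron-sulfur assembly, was lower in RTX than at day 0, at -1.22.

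The 14 genes of RNA polymerase I and its initiation factors had a median of 0.86 in RTX over DMSO, and the 31 of the small-subunit processome, which acts in ribosomal RNA processing, one of 0.76. Members whose values had been seen prompted these lists, so the medians were also taken without them. The other 10 genes of RNA polymerase I had a median of 0.38 in RTX over DMSO (interval -0.20 to 1.11) and 0.13 in RTX over day 0 (-0.06 to 0.59). The other 26 of the processome had a median of 0.70 in RTX over DMSO (0.28 to 1.28), above all 10000 matched lists, -0.56 in DMSO over day 0 and 0.17 in RTX over day 0 (-0.04 to 0.27). Of the CUL2 ligase, in which CUL2 prompted the list, TCEB1 stood at 2.20, VHL at 1.69, TCEB2 at 0.74 and RBX1, which other cullins also use, at -0.49 in RTX over DMSO, and these 4 had an interval of -0.49 to 2.20 around their median. The AP-2 adaptor without AP2S1 had a median of -0.17 in RTX over DMSO (interval -0.54 to 0.65). In RTX over day 0 its median was 0.15 (-0.02 to 1.36), and AP2M1 passed there beside AP2S1 when adjusted over the list alone.

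For the rise of chromosome 21 in RTX, the function of the single genes is argued against by the KRTAP genes, which encode hair-shaft proteins: the 48 on chromosome 21 stood 0.67 above the 30 on chromosome 17 (interval 0.47 to 0.94). Low or uneven guide abundance is argued against by 0 of 10000 matched random lists reaching the chromosome's median. Loss of the part of the chromosome beyond the cut alone would leave the genes between SLC19A1 and the telomere near 0, but these 13 genes had a median of 0.68 (interval 0.43 to 0.78). This test replaced an earlier one of the same explanation, the difference between the 207 genes before SLC19A1 and the 13 beyond it, which was 0.05 (interval -0.11 to 0.35) and narrowly missed its limit of 0.3, although the explanation needs about 0.73, the median of the 207. As a hypothesis that was not tested, a cut anywhere on chromosome 21 may lead to loss of a whole copy and with it of a copy of SLC19A1, which would need the copy number of chromosome 21 in single cells with known guides.

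Several lists of genes lost without drug were higher in RTX than in DMSO, while DNA replication, the spliceosome core and the ATR-CHK1 checkpoint stayed within the limits. One common reduction of divisions stays open: the share of the day 14 loss kept in RTX was 0.076 for the ribosome, 0.391 for the proteasome, 0.479 for RNA polymerase II, 0.544 for the spliceosome core, 0.549 for the mitochondrial list and 0.866 for DNA replication, and 4.48% of 10000 shuffles of the 263 genes over these 6 lists gave a range as large, or 2.23% with the ATR-CHK1 checkpoint, whose share was 1.23 (interval 0.207 to 2.85), which together do not decide. This test replaced a comparison of the lowest and highest share alone, whose difference was 0.79 (interval 0.47 to 1.65), and the shares depend on the scaling: with the non-targeting guides at 0, the ribosome's was 0.165, the range 0.621 and the shuffles as large 3.01%. Chance low reads of single guides in the shared DMSO library are argued against for the ribosome list as a whole. This list was fixed before the data were examined. Its 75 genes had a median of -0.83 in DMSO over day 0 (interval -0.99 to -0.53), below all 10000 lists matched on abundance and guide number. Of 10000 lists matched on the DMSO score, 0% reached its median in RTX over DMSO. In RTX over day 0 such lists put the ribosome at percentile 92.6, within the limits, but their choice uses the DMSO library. Lists matched on day 0 abundance and guide number, without that library, put it at percentile 10.3. The matching on the DMSO score was by deciles, so loss can still differ within the lowest one. How far the ribosome's rise exceeds that of other genes equally lost in DMSO therefore stays open. For Mediator, loss of the same genes in the DMSO library is a candidate explanation, since 36.5% of lists matched on the DMSO score reached its median. Such lists put Mediator at percentile 97.4 in RTX over day 0, just inside the limits, but their choice also uses the DMSO library. Against lists matched on day 0 abundance and guide number, Mediator was there at percentile 72.0. These values do not settle this explanation. Differences between single cultures cannot be seen.

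The transfer RNA genes were tested for loss of the same genes in the DMSO day 14 library. Values of 7 genes had been seen before the list was made, so the other 7 were used, with a median of 0.96 in RTX over DMSO (interval 0.24 to 1.09) and 6 of 7 above 0. Of 10000 lists matched on the DMSO score, 0.01% reached it, where the median of such lists was 0.16. These 7 genes had a median of 0.68 in RTX over day 0 (interval 0.11 to 0.87), a comparison without the DMSO library. As a hypothesis, loss of this modification may favour cells in RTX, and a second culture of each condition would be needed to test it.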
